A study of Mus musculus with 4 samples.

How the data were processed

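Gene expression was measured in 4 arrays of total RNA from cultured mouse bone marrow, 2 from control and 2 from Meis1-deleted cells. Per the labels, the RNA was amplified with a whole-transcript kit and labelled with biotin. Per the submitters' processing notes, Affymetrix Expression Console made the deposited values, which hold 1 log-scale level per probe set and array. The version, the summary method and the base of the logarithm are not given in the sources used here. The values, from 4.17 to 15.15 and in steps of 0.01, span what a base-2 logarithm of a scanner's readings spans, so they are read as log2 values throughout. The quartiles of the 4 deposited log2 distributions lay within 0.04 of each other, so no further normalization was applied before the tests. A difference of 1 on this scale is a 2-fold difference.

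The table held 35556 probe sets. Gene symbols came from the platform annotation, which listed 23410 of them, 21789 with 1 gene symbol and 1621 with several. The other 12146 probe sets were not listed there and are unnamed here. A probe set with several symbols was not named, which left out Cdkn1a, Pbx1, Mpl, Ly6a, Gapdh and the haemoglobin genes among others. Of the named probe sets, 21698 matched the RefSeq gene table of assembly GRCm38.p6 by Entrez number, and 0 symbols needed an update. No genome build is named for the array, so no coordinates are given. Where a gene had over 1 probe set, as 999 genes did, that with the highest mean over the 4 arrays was used. In 3 of those genes, probe sets differed between the groups by over 0.2 log2 in opposite directions. This gave 19938 genes, with no filter on level.

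Groups were taken from the sample titles. The numbers in the titles (Control_124, Control_180, Meis1-deleted_120 and Meis1-deleted_176) differ in every sample, so nothing paired the arrays. Nothing in the labels says that the 2 samples of a group came from separate mice or cultures. The controls differ in their pattern of sex-linked genes, so they came from different mice. P-values measure only the spread between these samples, which may be technical between the Meis1-deleted arrays. The comparison was fitted with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with a trend of the variance on the mean level. It was two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Standard errors (SE) and 95% intervals are those of the moderated limma test, which had 4.80 degrees of freedom. For arrays, their number limits the precision: with 2 against 2, the median SE of a difference was 0.124 log2, and the median 95% interval reached 0.32 log2, or 1.25-fold, to each side. An exact permutation test of 2 arrays against 2 cannot give a p below 0.333, so none was used.

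The test, the alternatives and 23 gene lists, with 1 more of sex-linked genes, were fixed before the data were examined. Together they held 607 memberships, of which 559 were measured, and 533 measured genes, 24 of them in over 1 list. The lists covered stem and progenitor, megakaryocyte, erythroid, neutrophil, monocyte, mast cell and eosinophil, lymphoid, and stromal genes. They also covered HIF subunits, hypoxia-inducible genes, glycolysis, antioxidant and oxidative phosphorylation genes, p53 targets and cyclin-dependent kinase inhibitors. The others held G1/S, G2/M, interferon-stimulated, unfolded protein and amino acid stress, immediate-early and heat shock, ribosome biogenesis and MYC target, and Hox and TALE genes, and genes earlier linked to MEIS1. Each list was tested against all other genes with camera (limma), with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 23 lists. It was tested again with a correlation estimated from the data, and with fry, which asks whether a list's genes move on balance one way.

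Genes named in the text follow a rule fixed in advance. It takes Meis1, Meis2, Meis3, Hif1a, Epas1, Flt3, Cdkn1a (not named on the array here), Cdkn2a, Pf4, Itga2b, Gata1 and Klf1, and up to 12 genes higher and 12 lower. Where fewer than 12 passed the threshold, the places went to the genes with the largest difference among those whose Meis1-deleted arrays both lay on the same side of both controls. Such genes also had to exceed the median level in the higher group, and are given as values that did not pass. In each list described, up to 4 members with the smallest unadjusted p are named. Genes named outside this rule are said to have been chosen after their values were seen.

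The tests were checked on simulated data in 20 draws with independent noise of the real genes' size and 200 of 19938 genes changed. The comparison recovered 42.3% of genes changed by 1.5-fold, 75.1% of those changed by 2-fold and 98.8% of those changed by 4-fold, and called 14 unchanged genes per draw. A list moved by 0.3 log2 was called in 20 of 20 draws. The noise was independent between genes, and each gene's moderated SD was taken as its true SD. Real arrays deviate in many genes together, so these shares do not give the power of the real comparison. In a further 100 draws, the arrays deviated from the gene means only along the 2 directions in which the real replicates differed, with no effect of genotype. Camera with the preset correlation then called a median of 9 of the 23 lists per draw, from 3 to 12. These draws take the spread of 2 replicate pairs as known.

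Alternatives changed 1 choice at a time. They were the variance trend, robust variances, genes above the median level alone, the mean of a gene's probe sets, quantile normalization, and arrays centred on their medians. Array weights, a block of nearby title numbers, each array left out in turn, all probe sets, an adjusted threshold of 0.1, a 1.5-fold minimum and the other list tests completed them. Tables were handled with pandas 2.3.3 in Python 3.11.15, and plots were drawn with matplotlib 3.10.9.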

Results

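Lineage-negative bone marrow cells from mice of the C57BL/6 strain were compared between a control and a Meis1-deleted group. Such cells are the fraction left when cells bearing markers of mature blood lineages are removed. Meis1 encodes a homeodomain transcription factor of the TALE class that is active in blood stem and progenitor cells. The deletable allele was combined with CreER, a recombinase that 4-OHT (4-hydroxytamoxifen) switches on. The labels call the controls wildtype and do not say whether they carried CreER. Cells of both groups were cultured for 48 hours with 4-OHT and the cytokines SCF, G-CSF and TPO before RNA was extracted. Each group had 2 samples, each on 1 array and named here by its title: Control_124 and Control_180, and Meis1-deleted_120 and Meis1-deleted_176. Expression values are on the log2 scale, and the median over 35556 probe sets was 8.05, 8.09, 8.09 and 8.06 in that order.

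The arrays did not group by genotype. Over all probe sets, the closest pair was Control_124 and Meis1-deleted_176, with 12 of 19938 genes at least 1 log2 apart. The Meis1-deleted arrays had 145 such genes between them and the controls had 331. Control_180 was furthest from the others, with 423 such genes against Meis1-deleted_176 and 254 against Meis1-deleted_120.

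Genes of the sex chromosomes separated Control_180 from the other arrays. Xist, the RNA that silences 1 X chromosome in female cells, had a level of 12.51 in Control_180 and of 5.86, 5.77 and 5.77 in Control_124, Meis1-deleted_120 and Meis1-deleted_176. The Y-linked gene Uty had a level of 5.67 in Control_180 and of 10.18, 10.45 and 9.88 in the same other arrays. Kdm5d (6.61 against 9.68, 9.71 and 9.80) and Eif2s3y (5.68 against 11.02, 11.14 and 10.71), both Y-linked, had the same pattern. Control_180 thus carried the female pattern and the other 3 arrays the male pattern.

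Meis1 itself was lower in the Meis1-deleted group, at 9.31 ± 0.51 (SD, n = 2) against 9.93 ± 0.29 (SD, n = 2) in controls, and the difference did not pass the test. Its probe set, 10384504, read 9.72 in Control_124, 10.13 in Control_180, 9.67 in Meis1-deleted_120 and 8.95 in Meis1-deleted_176. The difference was -0.62 log2, or 1.53-fold, with a 95% interval from -1.39 to 0.16 (limma, adjusted p = 0.999). The lower mean came mostly from Meis1-deleted_176, which lay 0.77 log2 below Control_124, and only 23 of 19938 genes lay further below Control_124 in that array. In Meis1-deleted_120 the level was 0.05 log2 below Control_124, and 6968 genes lay further below. Without Meis1-deleted_176 the difference was -0.26 log2, and without Meis1-deleted_120 it was -0.98 log2. The labels do not say which exons are removed, and a probe set of a whole-transcript array can miss the loss of a few, so these levels may not check the deletion. The related genes Meis2 (6.40 ± 0.050 against 6.21 ± 0.050, SD, n = 2) and Meis3 (7.83 ± 0.057 against 7.81 ± 0.021, SD, n = 2) did not pass either. Meis2 lay below the lower quartile of each array (6.57 or 6.59), so its difference says little.

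**Figure D1:**
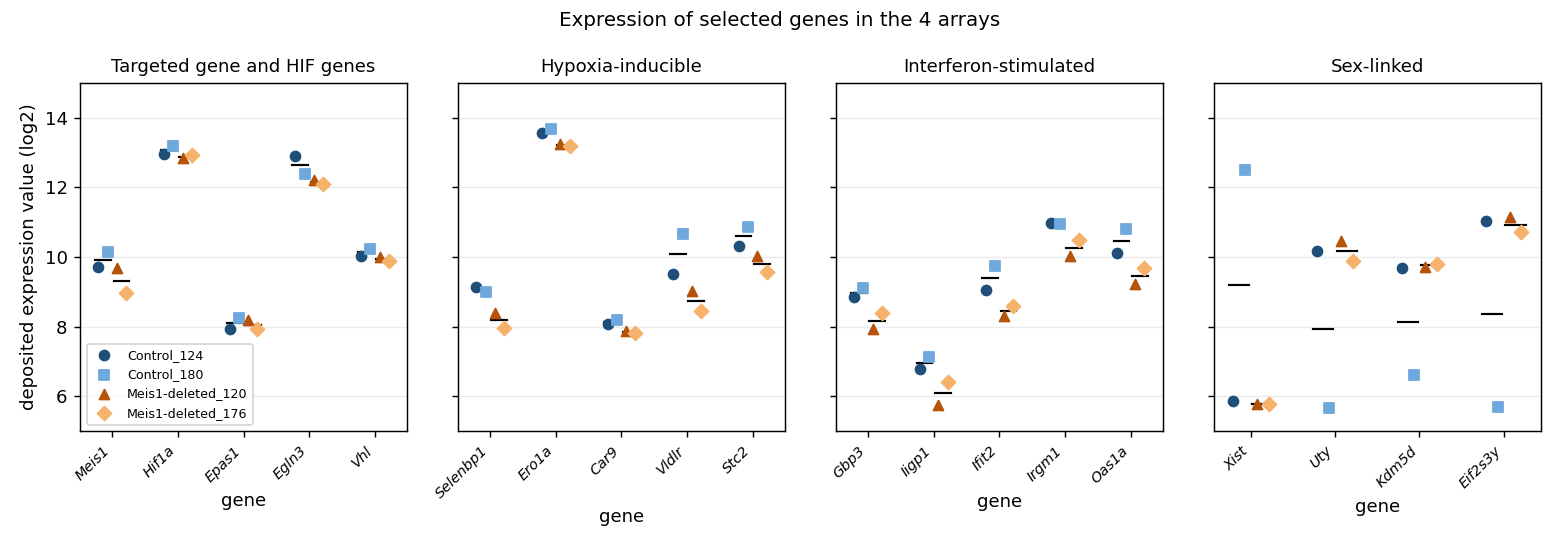
Deposited log2 expression of selected genes in the 4 arrays, with gene on the horizontal axis and points for Control_124, Control_180, Meis1-deleted_120 and Meis1-deleted_176; black bars mark group means. Selenbp1 has a mean of 9.07 in controls and of 8.18 in Meis1-deleted arrays, Meis1 is lowest in Meis1-deleted_176 at 8.95, and Xist stands at 12.51 in Control_180 alone.

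The comparison asked which genes differ between Meis1-deleted and control cells after the culture with 4-OHT. The genes with the largest differences were mostly lower in the Meis1-deleted group, with interferon-stimulated genes such as Ifit1, Irf7 and Oasl2 and the hypoxia-inducible gene Vldlr among them. No gene passed the test. With limma, 0 of 19938 genes had an adjusted p under 0.05, and the smallest adjusted p was 0.999. At an unadjusted p under 0.05 there were 444 genes, 236 higher and 208 lower, where chance alone gives 997. Of these, 64 also differed by at least 1.5-fold, 1 higher and 63 lower, and without Control_180 that count was 23. Without Control_124 it was 879, without Meis1-deleted_120 it was 32, and without Meis1-deleted_176 it was 125. In 2890 genes (14.5%) both Meis1-deleted arrays lay above both controls and in 2066 (10.4%) below, where chance gives 16.7% each way.

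The 12 lower genes that the rule named were led by Xist, at -3.42 log2 (SE 2.15), which differed through Control_180 alone. Lrmda was 3.99-fold lower (SE 0.57 log2), with levels of 10.10 and 11.01 in Control_124 and Control_180 and of 7.82 and 9.30 in Meis1-deleted_120 and Meis1-deleted_176. The interferon-stimulated genes among the 12 were Rtp4 at -1.64 log2 (SE 0.52), Oasl2 at -1.63 (SE 0.47), Irf7 at -1.58 (SE 0.60), Zbp1 at -1.36 (SE 0.55) and Ifit1 at -1.34 (SE 0.44). Oasl2 encodes an antiviral oligoadenylate synthetase-like protein, Irf7 a transcription factor that amplifies the interferon response, and Zbp1 a sensor of nucleic acids. Slfn4 (-1.85 log2, SE 0.71) and Ddx60 (-1.73 log2, SE 0.55), which interferon also induces, stood beside them but were not in the interferon list. Arg1, the arginase of myeloid cells, differed by -1.71 log2 (SE 0.55), with 10.52 and 11.90 in controls and 9.05 and 9.95 in Meis1-deleted arrays. Mirt2 differed by -1.57 log2 (SE 0.71) and Vldlr, a lipoprotein receptor induced by hypoxia, by -1.36 log2 (SE 0.43). All 12 differed by less against Control_124 alone, Mirt2 by -0.49 log2 and Slfn4 by -0.87 log2.

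Apart from Kdm5d, the 12 higher genes differed by less. Kdm5d came first at 1.61 log2 (SE 0.997), again through Control_180. Cd209a, a C-type lectin of dendritic cells, was 0.99 log2 higher (SE 0.35), at 9.45 and 8.52 in Meis1-deleted_120 and Meis1-deleted_176 against 8.23 and 7.77 in Control_124 and Control_180. Lpl, lipoprotein lipase, was 0.46 log2 higher (SE 0.23) and Ldlrad3 0.46 log2 higher (SE 0.21). The rest lay between 0.43 and 0.55 log2: Pop1, Znrd2, Smpd4, Bop1, Shmt1, Nol9, B4galt6 and Car12. Most of these differences came from Control_180: against Control_124 alone the 12 genes were higher by 0.015 (Bop1) to 0.76 log2 (Cd209a), and only Cd209a and Lpl (0.51) by over 0.22 log2.

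Among the 23 gene lists, camera with its preset correlation placed 14 past an adjusted p of 0.05, 10 lower and 4 higher in the Meis1-deleted group. With an estimated correlation 0 lists passed, at a smallest adjusted p of 0.508, and with fry 0 passed, at a smallest adjusted p of 0.653. In every list, 0 members changed over all genes tested and 0 adjusted over the list alone. Without Control_180 the preset test called 5 lists: interferon-stimulated, hypoxia-inducible, glycolysis, immediate-early and, then lower, G1/S genes. Only 2 lists, interferon-stimulated and hypoxia-inducible genes, were called with each of the 4 arrays left out in turn. In draws with no genotype effect, in which arrays deviated as the real replicates do, the preset test called a median of 9 lists, so its calls are given below with the estimated-correlation p and with the value without Control_180.

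**Figure D2:**
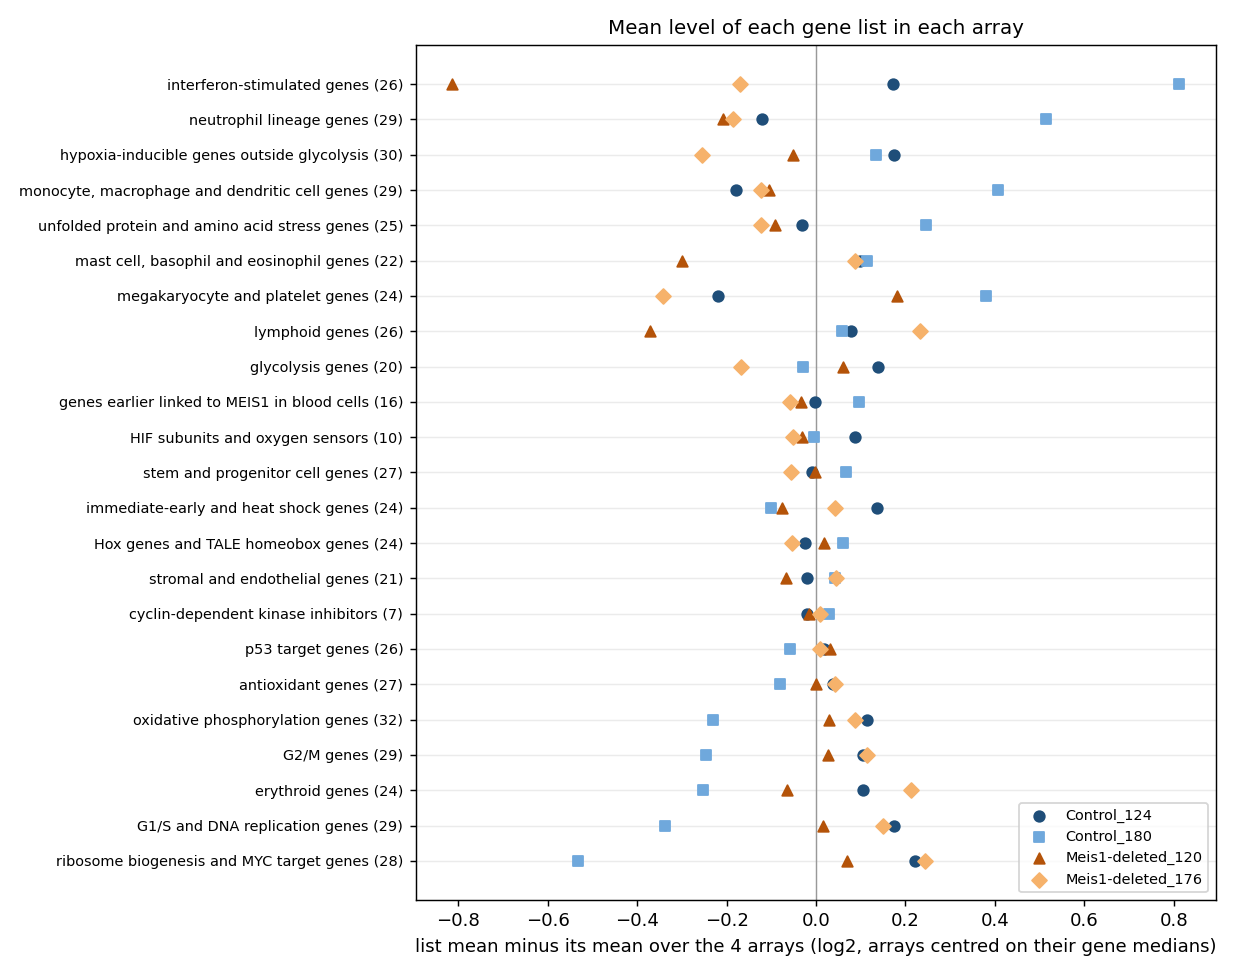
Mean level of each gene list in each array on the horizontal axis (log2, arrays centred on their gene medians, minus the list's mean over the 4 arrays), with lists on the vertical axis and their measured members in brackets. Interferon-stimulated and hypoxia-inducible genes are lower in both Meis1-deleted arrays than in both controls, while in ribosome biogenesis and MYC target genes Control_180 lies apart from the other 3 arrays.

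Hypoxia-inducible genes outside glycolysis were lower in Meis1-deleted cells. Of 30 measured members, 25 had a lower mean, 14 lay below both controls in both Meis1-deleted arrays, and 5 had an unadjusted p under 0.05. The mean difference was -0.32 ± 0.37 log2 (SD over members), with list means of 1.95 and 1.92 in Control_124 and Control_180 and of 1.73 and 1.53 in Meis1-deleted_120 and Meis1-deleted_176, counted from each array's gene median where positive values lie above it. Selenbp1, a selenium-binding protein, was at 8.18 ± 0.32 against 9.07 ± 0.092 (SD, n = 2), a difference of -0.89 log2 (SE 0.18). Ero1a, the oxidase that forms disulphide bonds in the endoplasmic reticulum, was at 13.22 ± 0.021 against 13.62 ± 0.064 (SD, n = 2), a difference of -0.40 log2 (SE 0.086). Car9, a carbonic anhydrase and a direct HIF target, differed by -0.30 log2 (SE 0.091). None of them passed, and the smallest p of a member adjusted over the list alone was 0.0909. The list test gave an adjusted p of 1.4e-09 with camera, and an adjusted p of 0.508 with an estimated correlation. Without Control_180 the mean difference was -0.31 log2, and 22 of the 30 members lay below Control_124 in both Meis1-deleted arrays. Without Control_124 the mean difference was -0.32 log2. The controls came to like list means partly through different members, as in Ak4 and Nos2, chosen after their values were seen. Ak4 read 12.83 in Control_124 and 11.43 in Control_180, against 12.38 and 11.91 in Meis1-deleted_120 and Meis1-deleted_176. Nos2 read 8.29 in Control_124 and 9.98 in Control_180, against 7.92 and 8.05. In the draws without a genotype effect, 0 of 100 gave a mean difference as large. Those draws take the spread of 2 replicate pairs as known, so their counts are not p-values. For this list the unadjusted p was 0.061 with camera and an estimated correlation, and 0.083 with fry.

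The genes that sense oxygen differed little as a list, most in Egln3. Egln3 and Egln1 are members of the hypoxia-inducible list too, so the lists are not independent. Among 10 HIF subunits and oxygen sensors, 7 had a lower mean, and the mean difference was -0.093 log2 (camera, adjusted p = 0.106). Hif1a, the inducible subunit of the hypoxia response, was at 12.88 ± 0.071 against 13.09 ± 0.16 (SD, n = 2), a difference of -0.21 log2 (SE 0.12). Against Control_124 alone Hif1a differed by -0.09 log2, and Egln3 by -0.765 log2. Epas1, which encodes HIF-2 alpha, differed by -0.04 log2 (SE 0.15). Egln3, a prolyl hydroxylase that is itself induced by HIF, differed by -0.50 log2 (SE 0.21), and Vhl by -0.19 log2 (SE 0.16). Glycolysis genes were lower by a mean of -0.12 log2, with 13 of 20 members lower, led by Aldoc at -0.96 log2 (SE 0.49), which read 10.67 in Meis1-deleted_120 and 9.22 in Meis1-deleted_176. Hk1 (-0.12 log2, SE 0.073) and Pfkp (-0.19 log2, SE 0.14) followed. The glycolysis list had an adjusted p of 0.0268 with camera and an adjusted p of 0.660 with an estimated correlation, and was -0.18 log2 without Control_180. The camera call ended without Meis1-deleted_176, where the difference was -0.0092 log2, and without Control_124, where it was -0.060 log2. It ended with a block of nearby title numbers too.

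Interferon-stimulated genes showed the largest difference of any list. All 26 measured members had a lower mean in the Meis1-deleted group, 24 lay below both controls in both Meis1-deleted arrays, and 18 had an unadjusted p under 0.05. The mean difference was -0.99 ± 0.37 log2 (SD over members), or 1.99-fold, with list means of 1.68 and 2.32 in Control_124 and Control_180 and of 0.70 and 1.34 in Meis1-deleted_120 and Meis1-deleted_176. Gbp3 and Irgm1 encode interferon-inducible GTPases, as does Iigp1. They differed by -0.81 log2 (SE 0.20), -0.71 log2 (SE 0.20) and -0.88 log2 (SE 0.24), and Ifit2, which binds viral RNA, by -0.95 log2 (SE 0.27). None passed, and the smallest p adjusted over the list alone was 0.0709. The list test gave an adjusted p of 1.3e-27 with camera and an adjusted p of 0.612 with an estimated correlation. Control_180 had the highest mean, and without it the difference was -0.65 log2, with 24 members still below Control_124 in both Meis1-deleted arrays. In the draws without a genotype effect, 8 of 100 gave a mean difference as large. The count was also 0 of 100 for HIF subunits and oxygen sensors and 7 of 100 for p53 target genes, at far smaller differences, and from 27 to 76 of 100 for the other lists.

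Lists of mature myeloid cells had a lower mean in the Meis1-deleted group, in neutrophil and monocyte genes mainly against Control_180. Neutrophil lineage genes differed by a mean of -0.40 log2, with 27 of 29 members lower (camera, adjusted p = 5.8e-07; adjusted p = 0.660 with an estimated correlation). Without Control_180 the mean was -0.061 log2, and the camera call ended. Cxcr2, the chemokine receptor of neutrophils, was at 11.52 ± 0.0071 against 12.58 ± 0.68 (SD, n = 2), and Il1r2, a decoy receptor for interleukin 1, differed by -0.42 log2 (SE 0.15). Monocyte, macrophage and dendritic cell genes differed by -0.24 log2, with 25 of 29 lower (camera, adjusted p = 4.5e-05; adjusted p = 0.679 with an estimated correlation), and by 0.080 log2 without Control_180. Ly86 (-0.55 log2, SE 0.28) and Ms4a6c (-0.56 log2, SE 0.30) had the smallest p among them. Mast cell, basophil and eosinophil genes differed by -0.22 log2, with 19 of 22 lower (camera, adjusted p = 1.0e-04; adjusted p = 0.508 with an estimated correlation), and by -0.19 log2 without Control_180. The basophil protease Prss34 differed by -0.37 log2 (SE 0.16), and eosinophil Prg2 by -0.59 log2 (SE 0.32), at 11.38 in Meis1-deleted_120 and 12.29 in Meis1-deleted_176. Without Meis1-deleted_120 the list differed by -0.024 log2, and the camera call ended.

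Growth and cell cycle genes were higher in the Meis1-deleted group through a low level in Control_180. All 28 ribosome biogenesis and MYC target genes had a higher mean, by 0.30 log2 on average (camera, adjusted p = 1.6e-05; adjusted p = 0.679 with an estimated correlation). List means were 3.70 in Control_124, 2.94 in Control_180, 3.54 in Meis1-deleted_120 and 3.72 in Meis1-deleted_176, so that without Control_180 the difference was -0.049 log2. Nolc1, a nucleolar chaperone, read 11.84 in Control_124 and 10.93 in Control_180, against 11.79 and 11.97 in Meis1-deleted_120 and Meis1-deleted_176. G1/S and DNA replication genes were 0.16 log2 higher (27 of 29 members; camera, adjusted p = 0.0125) and G2/M genes 0.13 log2 higher (26 of 29 members; camera, adjusted p = 0.00659). Both had an adjusted p of 0.712 with an estimated correlation, and without Control_180 they differed by -0.076 and -0.018 log2. Among them were the replicative helicase subunit Mcm2 (0.27 log2, SE 0.16) and the mitotic kinase Plk1 (0.27 log2, SE 0.20). Oxidative phosphorylation genes were 0.11 log2 higher, with 30 of 32 members higher (camera, adjusted p = 0.0175; adjusted p = 0.712 with an estimated correlation), and differed by -0.041 log2 without Control_180. The call also ended without Meis1-deleted_120, at 0.14 log2. Without Meis1-deleted_176 the camera calls for G1/S, G2/M and oxidative phosphorylation genes ended, at 0.082, 0.084 and 0.071 log2.

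The 2 stress lists had a lower mean, with members on both sides. The unfolded protein and amino acid stress list differed by -0.22 log2, with 18 of 25 members lower (camera, adjusted p = 0.00265; adjusted p = 0.508 with an estimated correlation). Without Control_180 it differed by -0.060 log2, and the camera call ended. The amino acid transporter Slc7a5 differed by -0.34 log2 (SE 0.12) and Chac1, which degrades glutathione, by -0.64 log2 (SE 0.28). Immediate-early and heat shock genes differed by -0.045 log2, with 17 of 24 lower (camera, adjusted p = 0.0341; adjusted p = 0.660 with an estimated correlation), and by -0.14 log2 without Control_180. Fos read 8.72 and 8.52 in Control_124 and Control_180 and 8.30 and 8.21 in Meis1-deleted_120 and Meis1-deleted_176, a difference of -0.37 log2 (SE 0.12). Without Control_124 the list differed by 0.048 log2 and without Meis1-deleted_120 by 0.019 log2, and the camera call ended in both cases, with quantile normalization and with a block of nearby title numbers. Its heat shock genes Hsph1, Hsp90aa1, Dnajb1, Hspa1a and Hspa8, chosen after their values were seen except Hspa1a, had a higher mean in the Meis1-deleted group, but against Control_124 alone only Hspa1a did. Without Meis1-deleted_176 the camera calls of both lists ended, at -0.21 and -0.11 log2.

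Megakaryocyte and platelet genes differed by -0.17 log2, with 20 of 24 lower (camera, adjusted p = 0.00235; adjusted p = 0.712 with an estimated correlation). The list means did not follow genotype: 1.88 in Control_124, 2.48 in Control_180, 2.28 in Meis1-deleted_120 and 1.76 in Meis1-deleted_176. Without Control_180 the difference was 0.15 log2, and without Meis1-deleted_176 it was 0.086 log2. Thbs1 (thrombospondin) differed by -0.62 log2 (SE 0.27), Itga2b (the platelet integrin alpha IIb) by -0.40 log2 (SE 0.30) and Pf4 (platelet factor) by -0.35 log2 (SE 0.27). Lymphoid genes differed by -0.15 log2, with 19 of 26 lower (camera, adjusted p = 0.0181; adjusted p = 0.679 with an estimated correlation). They differed by -0.13 log2 without Control_180 and by 0.16 log2 without Meis1-deleted_120, and the camera call ended in both cases and without Control_124 (-0.16 log2). It also ended among genes above the median level alone. Gzma (-0.44 log2, SE 0.11) and Il2rb (-0.38 log2, SE 0.13), genes of cytotoxic and natural killer cells, had the smallest p among them.

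Stem and progenitor cell genes did not pass the list test, at a mean difference of -0.069 log2 with 16 of 27 members lower (camera, adjusted p = 0.0552). Hoxa9, a partner of Meis1 in progenitors, differed by -0.24 log2 (SE 0.13), Tek by -0.21 log2 (SE 0.12), Mllt3 by -0.21 log2 (SE 0.13) and Flt3 by -0.37 log2 (SE 0.26). Flt3 did not separate the groups: it read 9.11 in Control_124 and 9.42 in Control_180, against 8.56 in Meis1-deleted_120 and 9.23 in Meis1-deleted_176. The 16 genes earlier linked to MEIS1 in blood cells differed by -0.10 log2 (camera, adjusted p = 0.0510) and the 24 Hox and TALE homeobox genes by -0.044 log2 (camera, adjusted p = 0.248). The Hox and TALE list differed by 0.0235 log2 without Control_180 and by -0.112 log2 without Control_124. The stem and MEIS1-linked lists passed under 3 and 6 of 13 alternatives, and without Control_180 differed by -0.0056 and -0.028 log2 (camera, adjusted p = 0.484 and 0.540). Hoxa5 read 7.55 and 7.59 in controls and 7.32 and 7.31 in Meis1-deleted_120 and Meis1-deleted_176. Erythroid genes differed by 0.14 log2, with 16 of 24 higher (camera, adjusted p = 0.0927), and by -0.017 log2 without Control_180 and -0.0069 log2 without Meis1-deleted_176. Of these, Rhag, part of the Rh complex of red cells, was 0.33 log2 higher (SE 0.079). It read 6.37 in Control_124 and 6.28 in Control_180, below the lower quartile of each array (6.57 or 6.59). A difference at such a low level says little. Klf1 differed by 0.17 log2 (SE 0.17) and Gata1 by -0.15 log2 (SE 0.26), both with the opposite sign against Control_124 alone.

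Antioxidant genes differed by 0.032 log2 (camera, adjusted p = 0.802). Within them the peroxiredoxin Prdx4 read 7.82 and 7.78 in controls and 7.47 and 7.48 in Meis1-deleted arrays. This difference of -0.33 log2 (SE 0.072) did not pass. Gclc and Hmox1 differed by 0.31 log2 (SE 0.18) and -0.29 log2 (SE 0.23), but against Control_124 alone by 0.105 and -0.015 log2. The p53 target genes differed by 0.032 log2 (camera, adjusted p = 0.639) and stromal and endothelial genes by -0.032 log2 (camera, adjusted p = 0.601). The 7 measured cyclin-dependent kinase inhibitors had a mean difference of -0.019 log2, a median of 0 and a camera direction of up (adjusted p = 0.879), so the measures differed in sign. Cdkn2a read 7.90 ± 0.014 against 7.90 ± 0.042 (SD, n = 2), with a 95% interval of the difference from -0.21 to 0.21 log2.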

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

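None of the alternatives here was added after the values were seen. The count of genes with an adjusted p under 0.05 stayed at 0 under all 15 alternatives. Not all of them could have changed it. The threshold of 0.1 and the 1.5-fold minimum used the main limma fit, whose smallest adjusted p was 0.999. Array weights came out equal within each group (0.74 for both controls and 1.36 for both Meis1-deleted arrays), so they could not weigh down Control_180 alone. The count of 64 genes with an unadjusted p under 0.05 and a 1.5-fold difference ran from 23 (without Control_180) to 879 (without Control_124) when arrays were left out, and from 47 to 94 under the other settings. The Meis1 difference kept its sign and its side of the threshold, from -0.98 to -0.26 log2 when arrays were left out and from -0.62 to -0.60 log2 otherwise. Where an array was left out, the lone array of its group was assumed to vary like the other group.

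The count of 14 lists became 0 with an estimated correlation and 0 with fry. It ran from 5 (without Control_180) to 12 (without Control_124) when arrays were left out, and from 12 to 16 under the other settings. Robust variances have no counterpart in camera, so that setting gave no list value. The mean differences of 8 called lists changed sign when an array was left out: immediate-early and heat shock genes (-0.14 to 0.048 log2), megakaryocyte (-0.49 to 0.15), monocyte (-0.56 to 0.080), oxidative phosphorylation (-0.041 to 0.25), G1/S (-0.076 to 0.39), G2/M (-0.018 to 0.28), ribosome biogenesis and MYC target (-0.049 to 0.65) and lymphoid genes (-0.45 to 0.16). Leaving out Control_180 changed the sign of 11 of the 23 list means and of 10 of 116 named genes. The cause was not tested beyond the values without Control_180. Of all list values under alternatives, 232 stayed on their side of the threshold, 46 lost a call in the same direction, 11 gained one, and 10 called values changed sign, of which only G1/S genes without Control_180 were still called; 1365 named gene values stayed on theirs, some with the opposite sign. The labels pair no samples. A block of nearby title numbers, which the labels do not describe as shared, gave 0 genes and 12 lists; within it interferon-stimulated genes differed by -0.98 (Meis1-deleted_120 minus Control_124) and -1.01 log2 (Meis1-deleted_176 minus Control_180). How far signal lay above background limits low genes: no background or detection value was used here.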

Other observations

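The tests of explanations in this part were chosen after the results were seen, and so were the genes named in it, while the setting without Control_180 was planned. Some neutrophil and stress genes stood apart in Control_180, and others of their lists did not. Retnlg, a granule gene of mature neutrophils, read 11.96 in Control_180 and 8.10, 9.51 and 7.60 in Control_124, Meis1-deleted_120 and Meis1-deleted_176, and Ly6g read 12.59 against 10.35, 10.42 and 10.07. The amino acid stress genes Trib3 (10.85 against 9.11, 9.08 and 9.03), Ddit3 (11.13 against 9.20, 9.69 and 9.35) and Cth (10.73 against 8.16, 8.38 and 8.02) had the same pattern. The transferrin receptor Tfrc read 10.15 in Control_180 and 12.28, 12.06 and 12.32 in the others, and the heat shock gene Hsph1 9.56 against 11.25, 10.84 and 11.29.

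Some B-lineage and eosinophil genes were lowest in Meis1-deleted_120, and others were not. Cd79a, part of the B cell receptor, read 8.19 there and 9.88, 9.78 and 10.47 in Control_124, Control_180 and Meis1-deleted_176, and the B cell transcription factor Ebf1 read 7.33 against 9.45, 8.83 and 9.91. Alox15 read 8.53 against 10.76, 10.64 and 11.58, and eosinophil peroxidase (Epx) 11.73 against 12.98, 12.99 and 13.16. Some platelet genes were higher in Control_180 and Meis1-deleted_120 than in the other arrays: Ppbp read 13.97 and 14.04 against 12.95 and 12.88, and Vwf 10.19 and 10.02 against 9.01 and 9.11 in Control_124 and Meis1-deleted_176. The red cell genes Alas2 (11.05 in Meis1-deleted_176, 9.97 in Control_124) and Slc4a1 (9.55 and 8.69) were lower in Control_180 (7.96 and 7.94) and Meis1-deleted_120 (7.68 and 7.98). Ciart, a repressor in the circadian clock, read 10.27 and 10.47 in controls and 9.60 and 9.43 in Meis1-deleted arrays, while the clock genes Nr1d1 and Dbp differed by 0.20 and -0.16 log2. The interferon genes Ifnb1, Ifna4 and Ifng differed by -0.035, 0.02 and -0.03 log2. Ifnb1 and Ifna4 read at most 6.40 and 6.50, below the lower quartile of each array (6.57 or 6.59). Ifng read at most 7.53, below each array's median. Differences at such low levels say little about interferon production.

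Hypoxia-inducible genes were lower in both Meis1-deleted arrays. Without Control_180 the mean difference was still -0.31 log2, over 2 SDs (0.14) from 0. That SD is the one between the 2 Meis1-deleted arrays alone, and the lone control left has no spread. Control_180 had a list mean of 1.92, below the 1.95 of Control_124, so it did not raise the mean of the controls. The values thus argue against Control_180 as the source of the list's mean difference in these arrays. Single members may still lean on it, as Nos2 did. Scaling left between the arrays would move genes of like level alike. The 1467 genes of the same level outside the lists differed by a median of 0.015 log2 (SD 0.20), against -0.32 log2 for the list. The quartiles of the deposited arrays lay within 0.04 of each other, and the median over all genes was also 0.015 log2. A median near 0 was thus all but fixed by the deposited scaling, and shows only that little scaling was left. What the submitters' processing did before deposit was not tested. Of the 3 splits of the 4 arrays, 1, the real one, gave a difference as large (0.32 against 0.10 for the highest other), and 3 splits are too few for a share under 0.05. An effect of Meis1 loss, one of CreER, which the labels do not place in controls, and differences in oxygen or cell density between cultures may each account for it, and none was tested.

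Interferon-stimulated genes were lower in both Meis1-deleted arrays. Fewer monocytes, macrophages and dendritic cells were not decided on: their list differed by -0.24 log2 over all arrays. Without Control_180 it differed by 0.080 log2, within its pooled SD of 0.29. That SD came mostly from the gap between the controls (0.59 log2, against 0.018 between the Meis1-deleted arrays), so this test could hardly decide. The monocyte list means were 2.30 in Control_124, 2.38 in Meis1-deleted_120 and 2.36 in Meis1-deleted_176. Against Control_124, a single array, these genes were thus not lower. The interferon list differed by -0.65 log2 without Control_180, within 2 SDs (0.45) of 0, so a high level in that array stays open as a cause. It leaned about as much on Meis1-deleted_120, which had the lowest list mean: without that array the list differed by -0.67 log2. Of the 3 splits, 1, the real one, gave a difference as large (0.99 against 0.67), and 3 splits are too few for a share under 0.05. An effect of Meis1 deletion, one of CreER, and a chance difference in interferon tone between mice or cultures, may each account for it.

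For the 12 other lists past the preset test, Control_180 as the cause stays undecided. Without it, 8 of the 12 lost at least 2/3 of their difference or changed sign, fewer than the rule asked for. Glycolysis, mast cell and eosinophil, lymphoid, and immediate-early genes did not, but leaned on other arrays. Without Meis1-deleted_120 the mast cell and eosinophil list differed by -0.024 log2 and the lymphoid list by 0.16 log2. Glycolysis genes differed by -0.0092 log2 without Meis1-deleted_176, and immediate-early genes by 0.048 log2 without Control_124. The sex of the mouse cannot be told apart from other features of Control_180, since 1 array had the female pattern of Xist and Y-linked genes. Of the 3 splits of the arrays, 2 gave a count as large as the 64 genes with an unadjusted p under 0.05 and a 1.5-fold difference. The split of Control_124 and Meis1-deleted_176 against Control_180 and Meis1-deleted_120 gave 481, which points to a structure of the samples other than genotype, and 3 splits are too few for a share under 0.05.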
